A study of Arabidopsis thaliana with 10 samples.

How the data were processed

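RNA from shoot apices of Arabidopsis thaliana seedlings was measured on 10 one-colour Agilent arrays, 1 array per RNA sample. The apices were taken 6 days after sowing by cutting off the cotyledons and the hypocotyl, and the seedlings had grown in constant light of about 50 µmol photons per square metre and second, per the labels' protocols. The wild type Columbia (Col) had 4 arrays, the mutant allele enf1-1 had 3 and the mutant allele enf1-6 had 3. The series' design text calls them independent experiments; neither it nor the labels say whether the plants of different samples were raised separately, so the p-values measure the spread between these samples.

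The intensity values of each spot were made with Agilent Feature Extraction 9.1.3.1, per the file headers. The processed signal intensity is the spot's mean brightness after a spatially detrended background was subtracted and a multiplicative trend within the array was divided out, with a surrogate for low signals, per the file headers. It was not scaled between arrays. The deposited value table of the series holds log10 values: each column equalled log10 of the processed signal of the same spot on the same array, except for 1 or 2 spots per array, so its scale is known, it is not centred and it has no direction to settle. Its column medians ran from 2.3 to 2.54, and it served as an alternative only.

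Each array held 39102 spots, of which 37685 were not controls. Control spots and spots that the scanner software marked as outliers were left out, and the spots of a probe were averaged, which gave 37353 probes. The processed signal of each array was divided by its own 75th percentile, which ran from 2698 to 4516, and taken to log2. A probe was tested where it lay well above background on at least 3 of the 10 arrays, which left 28926 probes. A gene with more than 1 tested probe was represented by the probe with the highest mean signal over all 10 arrays. This gave 28364 features: 22178 gene loci, 4295 probes that the array names only by a chromosome position, and 1891 other accessions. The array's locus names were matched to a reference gene table of assembly TAIR10.1, where 22016 loci matched and 9381 had a symbol. The array's own genome build is not given in the sources used here, so the table served only for names and for which genes neighbour each other. Of 486 loci with more than 1 tested probe, the probes of 388 gave the same call and those of 3 were called in opposite directions.

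A linear model with a mean for each of the 3 groups was fitted over all 10 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with 7 residual and 2.4 prior degrees of freedom. It gave 4 comparisons: the mean of both alleles against Col, each allele against Col, and enf1-6 against enf1-1. Adjusted p-values are Benjamini-Hochberg values over all features, with a threshold of 0.05. Standard errors (SE) come from limma, and SDs are between arrays of a group. On data simulated for the comparison of both alleles with Col, with 28364 features and 200 changed genes, the fit recovered 12.1% of genes changed by 0.5 on the log2 scale, 64.2% of those changed by 1 and 95.5% of those changed by 2, and it called 5 unchanged genes. The simulated data held far fewer changed genes than were called in the real data, so their threshold was stricter and these shares do not carry over to the real comparison.

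Gene lists fixed before the data were examined, 26 with 282 members of which 275 were tested, were compared with all other genes by limma's camera with a preset correlation of 0.01 between genes. The lists cover the GABA shunt, leaf polarity, meristem, growth, cell cycle, respiration, photosynthesis, hormones, stress, flowering, the clock and markers of other tissues and cell types. In these set tests a missing spot took the mean of its group's other arrays. Camera with an estimated correlation and fry were run beside it, and the adjusted p-values are over the 26 lists. YAB2, HSP17.4, HSP21, PRR9, NRT2.1, PLT1 and PLT2 were not tested. On simulated data with 1 shifted list, camera called that list and 0 others. The simulated genes varied independently of each other, while the real lists had estimated correlations of up to 0.63 (photosynthesis). This simulation therefore does not show how often camera calls correlated lists by chance.

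The genes named in the text follow a rule fixed before the data were examined. It takes ALDH5F1 and FIL. It takes the 12 largest rises and 12 largest falls among genes with a symbol that passed in both alleles and whose 6 enf1 arrays all lay on one side of the 4 Col arrays. It takes the 5 largest rises and falls of each allele, with the same demand for that allele, and up to 5 differences each way between the alleles that have a symbol, of which there were 0. From each list it takes up to 4 members that passed with the smallest p, or 2 where none passed. Genes named outside this rule are said to be so. Where the lower of the groups compared had any array on which the probe was not well above background, the fold is a bound, written "at least". For genes measured on some of those arrays this was decided after the values were seen. The bound sets the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal well above background and the probe's own. It allows for dim signals only and takes no account of the spread between arrays.

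The arrays came from 4 slides scanned on 2 days. Slide 1 held only Col and slide 2 only the mutants, both scanned on day 1, while slides 3 and 4, scanned on day 2, held all 3 groups. Slide and scan day were each tried as a block, and values were computed within each slide or day that held Col and both alleles. The fit with slide as a block takes its contrast of the mean of both alleles against Col from slides 3 and 4. For a single allele against Col it also draws on the difference between the alleles on slide 2. Other alternatives were normexp background correction (offset 50) with quantile normalization, quantile normalization of the processed signal, the deposited log10 values, other filters on dim probes, other rules for several probes, the replicate number as a block, only the groups compared, a trended and robust variance, array weights, a minimum change of 1 on the log2 scale, and leaving out each array in turn. Scan day as a block and day 1 alone were added after the data were seen. All 10 columns of the value table belonged to a sample used here.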

Results

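Transcript levels were compared between shoot apices of wild-type Col and of 2 mutant alleles of ENF1, enf1-1 and enf1-6, in 6-day-old Arabidopsis seedlings. ENF1 is ALDH5F1, the mitochondrial succinic semialdehyde dehydrogenase that carries out the last step of the GABA shunt. FIL, which the series title names, is a YABBY transcription factor gene expressed on the abaxial side of leaf primordia. There were 4 Col, 3 enf1-1 and 3 enf1-6 arrays, and between 71.7% and 82.2% of the spots of an array lay well above background. The number of arrays limits the precision. On the first principal component, which held 49.4% of the variance, the Col arrays lay between -82.6 and -44.1 and the enf1 arrays between 5.9 and 60.3. The enf1 array nearest to Col was enf1-1 replicate 3, at 5.9.

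The mutated gene was lower in every enf1 array than in every Col array. ALDH5F1 (AT1G79440) fell 14.2-fold in enf1-1 (log2 change -3.83, SE 0.33, adjusted p = 0.00014, n = 3 against 4) and 3.53-fold in enf1-6 (log2 change -1.82, SE 0.33, adjusted p = 0.004, n = 3 against 4). Its log2 values were 1.27 to 1.88 in Col, -2.8 to -1.35 in enf1-1 and -0.35 to -0.24 in enf1-6. The difference of 2.01 between the alleles did not pass when adjusted over all features (adjusted p = 0.41). This does not show that the alleles are alike at this gene, since their array values did not overlap. The lesions are not stated in the labels, so a probe outside a lesion checks the labels only as far as the lesion lowers the transcript. The change averaged over the alleles was -2.83 over all arrays, -2.81 within scan day 1, -2.95 within day 2 and with slide as a block, -3.42 within slide 3 and -2.47 within slide 4. FIL (AT2G45190) differed by 0.02 between the mean of both alleles and Col (SE 0.13, adjusted p = 0.91), by 0.27 within day 1 and by -0.18 within day 2, and its sign turned under several alternatives.

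**Figure D1:**
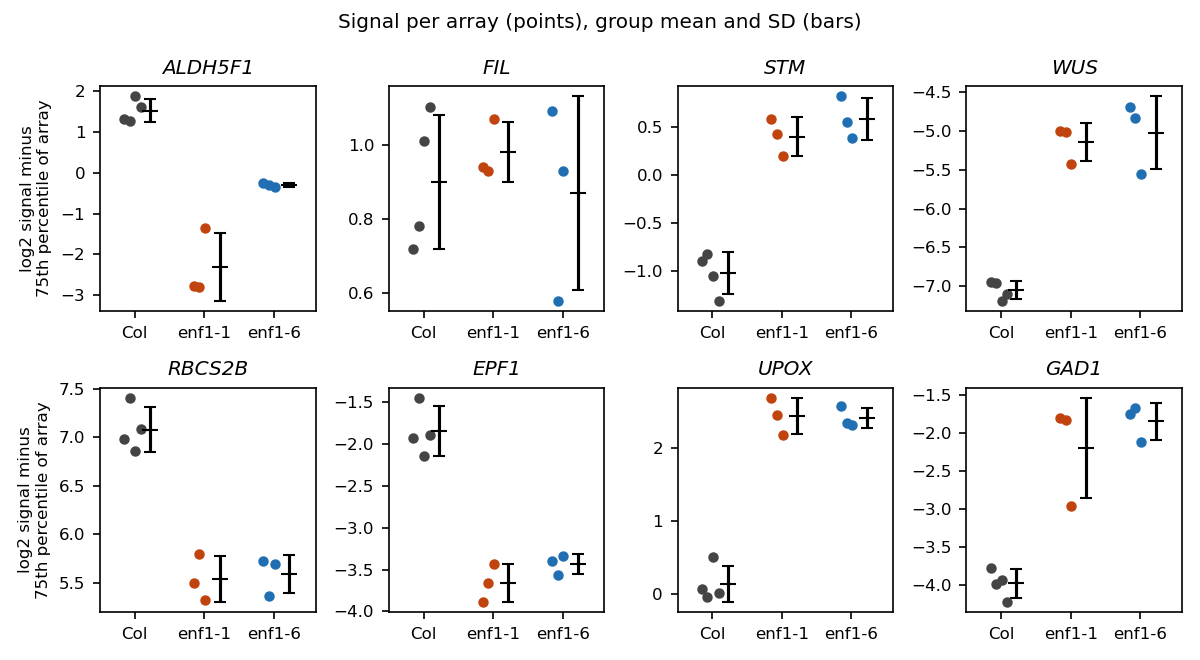
Log2 signal minus the array's 75th percentile for 8 genes, with a point per array, and the mean and SD of each group beside the points (n = 4 Col, 3 enf1-1, 3 enf1-6). ALDH5F1, RBCS2B and EPF1 lie lower, and STM, WUS, UPOX and GAD1 higher, in every enf1 array than in every Col array, while the groups overlap for FIL (log2 change 0.02).

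The comparison of both alleles with Col asks which genes differ in the apex when ENF1 is mutated. Among genes with a symbol, most of the largest rises were in genes not well above background on every Col array. WRKY50, a WRKY transcription factor gene, rose at least 44.5-fold (fitted log2 change 6.94, SE 0.25, adjusted p = 2.2e-06). GEX1, which encodes a membrane protein of gametes, rose at least 43.1-fold (6.01, SE 0.23, adjusted p = 2.5e-06). CPL5, a phosphatase-like gene, rose at least 8.24-fold. None of these 3 was well above background on any Col array. CHR34, a chromatin remodelling factor gene, rose at least 31-fold, with 1 of 4 Col arrays well above background.

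TIM17-1, a subunit of the mitochondrial inner membrane translocase, rose at least 54.7-fold (log2 change 5.79, SE 0.27, adjusted p = 4.6e-06), and SRO3 rose at least 36.9-fold, each measured on 3 of 4 Col arrays. DREB19, an AP2/ERF transcription factor gene, rose 48.8-fold, and NAC085, a NAC transcription factor gene measured on 2 of 4 Col arrays, rose at least 40.2-fold. The cysteine protease gene CEP2, measured on 1 of 4 Col arrays, rose at least 29.6-fold. The homeodomain gene HDG7 and the arabinogalactan protein gene AGP5 each rose 31.2-fold. NDB4, an alternative NAD(P)H dehydrogenase of mitochondria, rose at least 22-fold, with 3 of 4 Col arrays well above background.

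The largest falls among genes with a symbol included DOT3, a gene of vein patterning, which fell at least 5.37-fold (fitted log2 change -3.42, SE 0.42, adjusted p = 0.00042) and was well above background on 0 of 3 enf1-1 and 1 of 3 enf1-6 arrays. The B-box gene BBX17 was 10.1-fold lower (log2 change -3.34, SE 0.21, adjusted p = 1.5e-05), and AIR3, a subtilisin-like protease gene, was 9.99-fold lower. The receptor-like kinase gene CRK21 was at least 8.56-fold lower, with 1 of 3 enf1-1 arrays well above background. PYL10, an abscisic acid receptor gene, was at least 3.62-fold lower, with 1 array of each allele well above background. GDPD6 was 6.55-fold lower and the carbonic anhydrase gene ACA2 6.27-fold lower. RIC10 was 5.92-fold and the zinc transporter gene ZIP7 5.84-fold lower. RGTA2 fell at least 3.11-fold and PORA, a protochlorophyllide oxidoreductase measured on 3 of 4 Col arrays, at least 1.4-fold, both on 0 enf1 arrays well above background. ALDH5F1 also belonged to these 12 falls. All of these rises and falls passed in each allele, and all 6 enf1 arrays lay on one side of the 4 Col arrays.

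Genes of the meristem and of organ boundaries rose together. Of 14 tested, 11 rose and 1 fell, and the same numbers passed when adjusted over the list alone. WUS, the stem cell organiser gene, rose at least 3.92-fold (log2 change 1.97, SE 0.18, adjusted p = 8.9e-05, 3 of 4 Col arrays well above background). The homeobox gene STM rose 2.85-fold and its relative KNAT1 2.59-fold. The boundary gene CUC1 rose 3.01-fold. CLV3, a peptide gene of the stem cells, was the member that fell, by 0.57 on the log2 scale, and it is named here outside the rule, after its value was seen. The list's median change was 0.97, and camera placed it above other genes (adjusted p = 8.2e-05; adjusted p = 0.54 with an estimated correlation). The median was 1.14 within day 1, 1.02 within day 2 and with slide as a block, 0.93 within slide 3 and 0.95 within slide 4.

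Auxin genes moved upward as well. Of 14 tested, 10 rose and 0 fell, and 13 rose when adjusted over the list alone. The conjugating enzyme gene GH3.3 rose 1.65-fold, MP, an auxin response factor gene, 1.64-fold, IAA5 1.98-fold and YUC1, an auxin synthesis gene, 1.61-fold. The median change was 0.66 (camera adjusted p = 0.00012; adjusted p = 0.47 with an estimated correlation), with 0.6 within day 1, 0.71 within day 2 and with slide as a block, 0.63 within slide 3 and 0.8 within slide 4. Of 10 cytokinin genes, 5 rose and 1 fell, over all genes and adjusted over the list alone, and the list did not pass (camera adjusted p = 0.26). IPT3, a cytokinin synthesis gene, rose 2.61-fold, and the response regulator genes ARR5 and ARR6 rose 2.65-fold and 2.2-fold, while ARR16 fell 3.65-fold. Of 8 gibberellin genes, 3 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.53). GA20OX2, a synthesis gene, rose 3.7-fold, GA2OX2, which encodes an inactivating enzyme, 3.27-fold and GASA4 2.16-fold, and GA3OX1, the last synthesis step, fell 1.99-fold.

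Photosynthesis genes fell. Of 17 tested, 0 rose and 15 fell, over all genes and adjusted over the list alone. RBCS2B, a Rubisco small subunit gene, was 2.87-fold lower (log2 change -1.52, SE 0.14, adjusted p = 0.00012), and the light-harvesting genes LHCA2, LHCB6 and LHCB4.1 were 2.47-fold, 2.41-fold and 1.98-fold lower. The list's median was -1.17 (camera adjusted p = 2.4e-08; adjusted p = 0.57 with an estimated correlation). It was -0.93 within day 1, -1.1 within day 2 and with slide as a block, -1.05 within slide 3 and -1.14 within slide 4. Stomatal lineage markers fell too: 7 of 10 fell and 0 rose, and 9 fell when adjusted over the list alone. SDD1 was 3.53-fold lower, the peptide gene EPF1 3.24-fold lower, MUTE, a transcription factor gene of the guard mother cell, 3.06-fold lower and MYB60 1.84-fold lower. Their median was -1.06 (camera adjusted p = 1e-05; adjusted p = 0.47 with an estimated correlation), with -1.43 within day 1, -0.88 within day 2 and with slide as a block, -0.93 within slide 3 and -0.79 within slide 4.

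Of 9 abaxial leaf genes tested, 3 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.41). KAN1 rose 1.56-fold, KAN4 1.41-fold and YAB5 1.37-fold. Of 12 adaxial genes, 1 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.66). SGS3, of the trans-acting small RNA pathway, rose 1.43-fold, and the HD-ZIP III genes PHB and REV were 1.72-fold and 1.33-fold lower. Among 14 leaf growth regulators, 6 rose and 4 fell, and 7 rose and 4 fell when adjusted over the list alone (camera adjusted p = 0.5). The AINTEGUMENTA-like genes AIL7 and AIL6 rose 1.85-fold and 1.52-fold, and TCP3 and TCP4, which restrain leaf growth, fell 2.13-fold and 2.06-fold. Of 16 genes of the cell cycle and DNA replication, 1 rose and 6 fell, or 2 and 8 adjusted over the list alone (camera adjusted p = 0.26). The riser was CYCB1;1, a mitotic cyclin gene, at 1.94-fold, while AUR2 and CYCB2;1 were each 1.51-fold and CDKB2;2 1.37-fold lower.

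**Figure D2:**
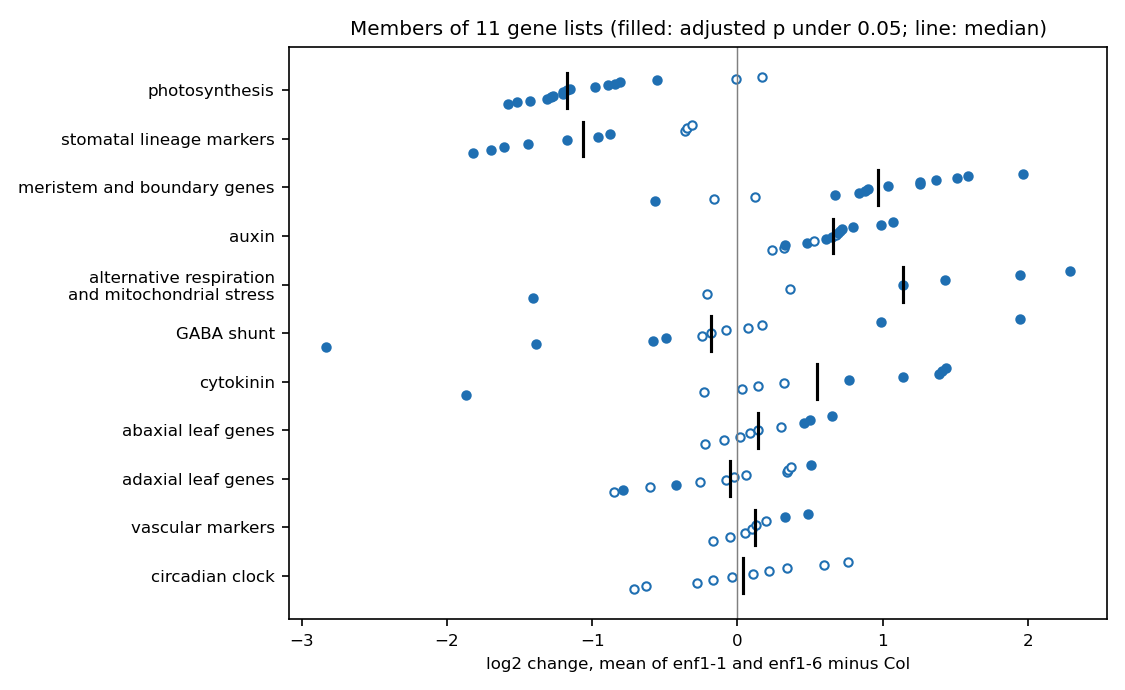
Log2 change, mean of enf1-1 and enf1-6 minus Col, of each tested member of 11 gene lists, with a point per gene (filled where the adjusted p is under 0.05) and a line at the list's median. Most photosynthesis genes (median -1.17) and all stomatal lineage genes (median -1.06) lie left of 0, and most meristem (median 0.97) and auxin genes (median 0.66) lie right of it, while no clock gene passed.

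In the GABA shunt, 2 of 11 genes rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.27). The glutamate decarboxylase gene GAD1 rose 3.86-fold (log2 change 1.95, SE 0.23, adjusted p = 0.00034). Besides ALDH5F1, the succinic semialdehyde reductase genes GLYR2 and GLYR1 fell, 2.62-fold and 1.4-fold. Of 7 genes of alternative respiration and mitochondrial stress, 4 rose and 1 fell, and 5 rose and 1 fell when adjusted over the list alone. The oxidative stress gene UPOX rose 4.88-fold, the alternative dehydrogenase gene NDB2 3.87-fold, the alternative oxidase gene AOX1A 2.7-fold and the transcription factor gene NAC013 2.2-fold. This list did not pass over both alleles (camera adjusted p = 0.08, median 1.14), while it passed with slide as a block (adjusted p = 0.038). Over all arrays its adjusted p was 0.66 with an estimated correlation. Of 15 TCA cycle and glutamate genes, 4 rose and 1 fell, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.26). The glutamate dehydrogenase genes GDH2 and GDH1 rose 1.79-fold and 1.62-fold and the citrate synthase gene CSY4 1.28-fold, and GLU1, a glutamate synthase gene, fell 2.02-fold. Of 15 other aldehyde dehydrogenases and aldo-keto reductases, 3 rose and 2 fell, or 3 and 3 adjusted over the list alone (camera adjusted p = 0.99). ALDH2B7 rose 2.14-fold and AKR4C8 2.06-fold, while ALDH3I1 and ALDH11A3 fell 1.83-fold and 1.52-fold. Of 15 oxidative stress genes, 2 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.99). The kinase gene OXI1 rose 6.77-fold and the glutathione transferase gene GSTU24 3.36-fold, and the chloroplast superoxide dismutase gene CSD2 was 5.06-fold lower.

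The other stress, hormone, flowering and clock lists are set here against the 27.4% of all features that passed. Of 11 salicylate and immune genes, 0 rose and 2 fell, also adjusted over the list alone (median 0.29, camera adjusted p = 0.99): PAD4 was 1.75-fold and ICS1, a salicylate synthesis gene, 1.74-fold lower. Among 8 jasmonate genes, PDF1.2A rose 6.51-fold and LOX2, a lipoxygenase gene, fell 5.66-fold, also adjusted over the list alone (1 up, 1 down; camera adjusted p = 0.99). Of 10 abscisic acid and dehydration genes, ADH1 rose 2.35-fold and RD22 1.46-fold, and the same 2 passed adjusted over the list alone (camera adjusted p = 0.64). Of 6 heat shock genes, HSP90.1 rose 1.69-fold and HSP17.6A at least 1.89-fold, with 0 of 4 Col and 2 of 3 arrays of each allele well above background; 2 passed adjusted over the list alone (camera adjusted p = 0.41). Of 8 anthocyanin genes, PAP1, a MYB regulator, fell 1.61-fold, but 0 passed adjusted over the list alone (camera adjusted p = 0.5). Of 10 flowering genes, 3 rose and 4 fell, or 3 and 5 adjusted over the list alone (camera adjusted p = 0.55). FLC, a floral repressor, rose 2.31-fold, and SPL3, FUL and SOC1 fell 4.05-fold, 2.82-fold and 1.59-fold. None of 10 clock genes passed limma's test, over all genes or adjusted over the list alone (camera adjusted p = 0.99), and the smallest p were those of RVE8 (log2 change -0.71, adjusted p = 0.12) and ELF4 (0.76, adjusted p = 0.14).

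Markers of other tissues gave the following. Of 5 root markers tested, 2 rose, also adjusted over the list alone (camera adjusted p = 0.21): the beta-glucosidase gene PYK10 2.68-fold and COBL9 2.57-fold. Of 8 vascular markers, XCP1 rose 1.4-fold and VND7 1.25-fold, also adjusted over the list alone (camera adjusted p = 0.5). Of 4 trichome markers, GL3 rose 1.33-fold and GL1 1.32-fold, also adjusted over the list alone (camera adjusted p = 0.64). Of 8 embryo and seed storage markers, CRU3, measured on 1 of 4 Col arrays, rose at least 1.8-fold, while 0 passed adjusted over the list alone (camera adjusted p = 0.41). The median changes of these lists were 0.36, 0.12, 0.2 and 0.72, against 0.06 for all features.

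In all, 7760 of 28364 features changed, 4229 higher and 3531 lower in enf1. The 6 enf1 arrays all lay on one side of the 4 Col arrays for 5987 features, or 21.1%, where chance gives 0.952%. The count was 4859 with slide as a block, 3716 within day 2 and 1218 within day 1. Of the 7760, 7719 had a value within day 1 and 7755 within day 2, each with the sign of the full fit, while 12 had the opposite sign within slide 3 and 8 within slide 4. The same arrays make up the full fit that chose these features, so this is no independent test. With slide as a block, PYL10, YAB5, REV, PHB, CYCB2;1, ALDH11A3, GDH2, CSY4, ARR6, PAD4, PDF1.2A, ADH1, RD22, HSP17.6A, PAP1, SOC1, FUL, COBL9, XCP1, VND7, GL1 and CRU3 kept their direction but no longer passed. Leaving out 1 array, for some choice of it, ended the calls of KAN4, REV, PHB, CDKB2;2, CSD2, PAD4, PDF1.2A, ADH1, RD22, HSP90.1, HSP17.6A, PAP1, VND7, GL1, GL3 and CRU3. On the deposited values, which are not scaled between arrays, the median of all features moved from 0.06 to -0.07, and 1881 were called higher and 2800 lower. Camera called 4 of 26 lists, 0 with an estimated correlation, and fry called 10. Fry does not set a list against the other genes. Besides the 4, it called alternative respiration (adjusted p = 0.0016), root markers (0.0029), abaxial (0.0031), gibberellin (0.029) and heat shock genes (0.044) upward. It called the GABA shunt, which includes ALDH5F1, downward (0.0031). In 51 of 100 splits of the arrays at least 4 lists passed camera, so the number of list calls was not above what chance gives. For oxidative stress the median was negative (-0.05), like camera's direction, and the mean positive (0.07). Camera's direction was down where median and mean were positive for aldehyde dehydrogenases (0.02 and 0.07), jasmonate (0.31 and 0.21) and the clock (0.04 and 0.02).

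In enf1-1 against Col, ALDH5F1 showed the largest fall among genes with a symbol (14.2-fold), followed by DOT3 (at least 6.01-fold), CRK21 (at least 9.28-fold), BBX17 (9.2-fold) and AIR3 (7.88-fold), in the order of the fitted change. The largest rises among them were WRKY50 (at least 52.4-fold), GEX1 (at least 47.6-fold), CHR34 (at least 33.3-fold), DREB19 (58.7-fold) and TIM17-1 (at least 54.3-fold), in the same order. Photosynthesis (median -1.43) and stomatal lineage genes (-1.08) were lower, and meristem (0.92), auxin (0.6) and alternative respiration genes (1.15) were higher. Their camera adjusted p-values were 5.3e-11, 4.2e-06, 5.8e-05, 5.8e-05 and 0.04, each with an adjusted p of 0.4 with an estimated correlation except alternative respiration with 0.47. In total 5057 features changed, 2423 higher and 2634 lower. Which direction had more depended on the setting: more were higher on the deposited values (1654 and 1261 lower), with array weights (4086 and 3553), with normexp and quantile (3064 and 2948), without Col replicate 2 (2720 and 2647), within day 2 (647 and 578), within day 1 (423 and 155) and, by 2952 to 2949, with scan day as a block, the last 2 settings chosen after seeing the data. The count was 3336 with slide as a block, 1225 within day 2 and 578 within day 1, and 3134 without enf1-1 replicate 1. AIR3 no longer passed in enf1-1 with slide as a block.

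In enf1-6 against Col, the largest rises among genes with a symbol were again WRKY50 (at least 37.9-fold), GEX1 (at least 39.1-fold), CHR34 (at least 28.8-fold), TIM17-1 (at least 55.1-fold) and SRO3 (at least 35.4-fold). AIR3 was 12.7-fold lower, BBX17 11.1-fold lower and DOT3 at least 4.79-fold lower, the last with 1 of 3 enf1-6 arrays well above background. NF-YC12, a nuclear factor Y subunit gene, was 10.7-fold lower (log2 change -3.43, SE 0.94, adjusted p = 0.027), and PCC1, a pathogen-responsive gene, 10.3-fold lower (-3.36, SE 1.06, adjusted p = 0.045). Their changes in enf1-1 were -0.86 and -1.01, and the differences between the alleles did not pass (adjusted p = 0.72 for each). Neither NF-YC12 nor PCC1 passed with slide as a block, or without any 1 of the 3 enf1-6 arrays. Photosynthesis (median -0.87) and stomatal lineage genes (-1.04) were lower, and meristem (1.17) and auxin genes (0.68) higher, with camera adjusted p-values of 9.1e-06, 5.3e-05, 6.6e-05 and 0.00072. With an estimated correlation the adjusted p was 0.62 for photosynthesis and 0.52 for the other 3. In total 7225 features changed, 4014 higher and 3211 lower, which made 55.6% higher. Genes at the start of chromosome 3, described below, were shifted upward in this allele. Their part in these rises, and in those for the mean of both alleles, was not counted. On the deposited values the median of all features moved from 0.09 to -0.23, and 1115 were called higher and 3282 lower, which made 25.4% higher. The count was 3716 within day 2 and 396 within day 1, and 4516 and 4380 without enf1-6 replicate 1 and 2.

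The same direction prevailed in both alleles. In both, 4377 features passed, 2148 higher and 2229 lower, and 0 passed in opposite directions. This count was 2903 without enf1-1 replicate 1, 2963 with slide as a block, 2210 on the deposited values, 1153 within day 2 and 288 within day 1, the last with 225 higher and 63 lower, and which direction had more depended on the setting here too. Independent lists of these sizes would share 343 rises and 298 falls. Simulated unchanged groups against the same Col arrays shared at most 0 calls in 20 draws. Across features, which are not independent replicates, the changes of the 2 alleles correlated with r = 0.87, against 0.43 simulated with unchanged groups. Their covariance was 0.426 against 0.0324 simulated, a difference of 0.394. With the Col arrays split 2 and 2 between the alleles, r was 0.64 to 0.81, the covariance 0.356 to 0.412 and the shared calls 2370 to 2822 over 6 splits. The draws and the splits allow for the shared Col arrays only. Arrays of enf1-1 and enf1-6 with the same number also shared a slide, and their deviations from the group means correlated with r = 0.22 to 0.41. A part of the shared calls from slide effects is therefore not excluded.

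**Figure D3:**
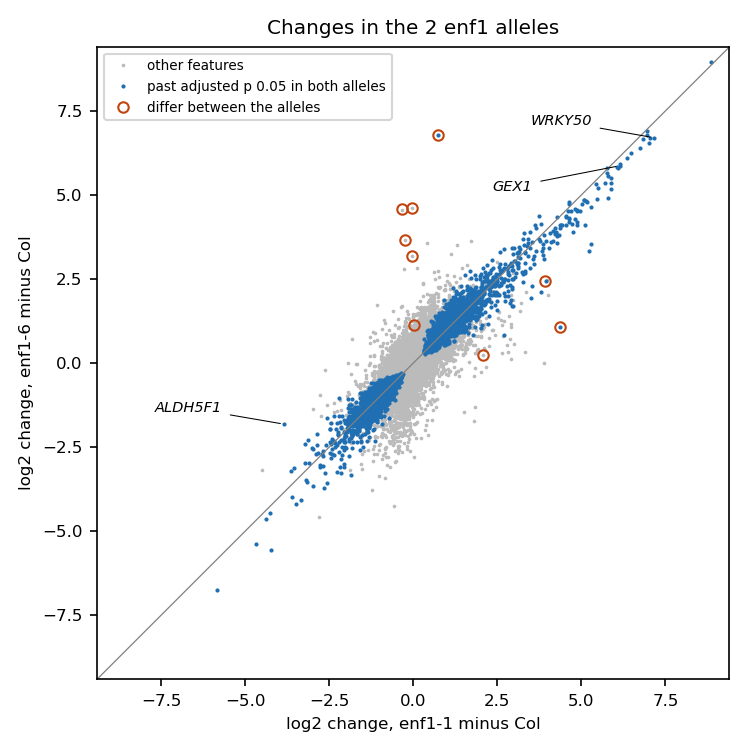
Log2 change of each of 28364 features in enf1-1 minus Col (horizontal axis) and enf1-6 minus Col (vertical axis), with features that passed in both alleles in blue and the 9 that differ between the alleles circled. The 4377 shared calls lie along the diagonal, 2148 above 0 and 2229 below 0 on both axes.

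Between enf1-6 and enf1-1 the test of the difference itself called 9 features, 6 higher and 3 lower in enf1-6, and 1933 had an unadjusted p under 0.05. None has a symbol, so the 4 loci among them are named here after their values were seen. AT5G24240 was 66.9-fold higher in enf1-6 (log2 difference 6.06, SE 0.2, adjusted p = 1.5e-06), and its neighbour AT5G24250 was at least 6.28-fold higher, with 0 arrays of enf1-1 or Col well above background. AT3G01345 was 29.8-fold higher (4.89, SE 0.12, adjusted p = 2e-07) and AT3G06145 2.17-fold higher (1.12, SE 0.13, adjusted p = 0.027). Camera called 4 lists between the alleles. Photosynthesis (median difference 0.43, adjusted p = 1.9e-05; adjusted p = 0.86 with an estimated correlation) and seed storage markers (0.6, adjusted p = 0.044; adjusted p = 0.86 with an estimated correlation) were higher in enf1-6. Adaxial genes (-0.15, adjusted p = 0.044; adjusted p = 0.55 with an estimated correlation) and anthocyanin genes (-0.21, adjusted p = 0.046; adjusted p = 0.86 with an estimated correlation) were lower in enf1-6. Fry called 0 lists. The count of features was 4 with slide as a block, 3 within day 2 and 4 to 9 with 1 array left out. It was 12 with quantile normalization or slide as a random block and 14 with array weights.

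Genes at the start of chromosome 3 were higher in enf1-6 as a block. This was examined after the values were seen, with the gene order of assembly TAIR10.1. The tested genes were parted into runs of 100 neighbours. The first 5 runs of chromosome 3, 500 genes from AT3G01015 to AT3G06350, had median differences between enf1-6 and enf1-1 of 0.37 to 0.43, and the other 216 runs had -0.06 to 0.19. Against Col, the medians of these 5 runs were 0.34 to 0.52 in each enf1-6 array and -0.05 to 0.15 in each enf1-1 array. The medians of the other runs reached 0.45 in an enf1-6 array and 0.29 in an enf1-1 array, so against Col the ranges overlap. The run on chromosome 2 from AT2G05320 to AT2G07719 had 0.35 in enf1-6 and 0.23 in enf1-1. The next run, from AT3G06360 to AT3G07340, had a median difference of 0.03. By locus number MUTE, NAC044 and 2 of the 4 loci above, AT3G01345 and AT3G06145, lie in this stretch.

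**Figure D4:**
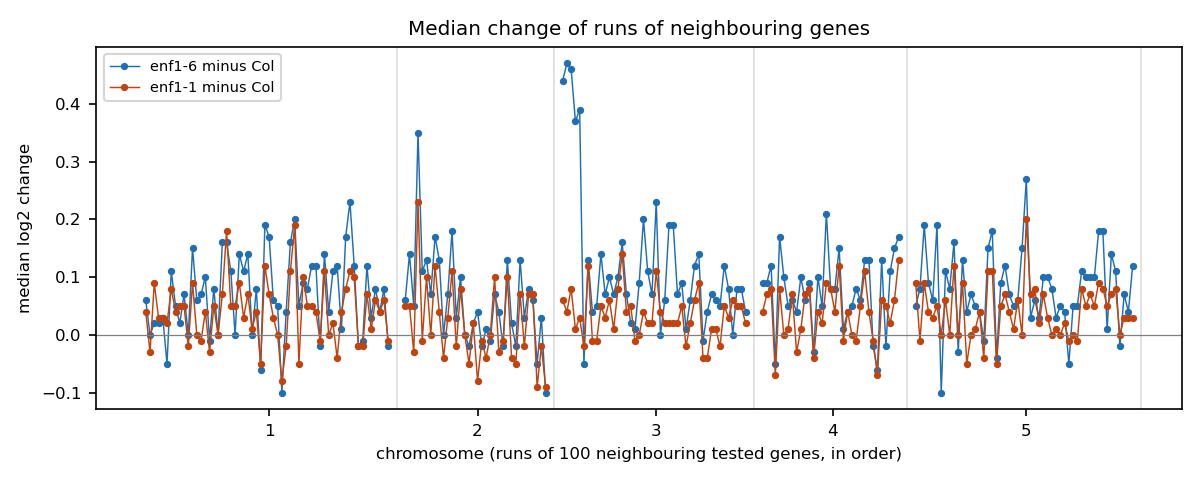
Median log2 change of runs of 100 neighbouring tested genes in chromosome order, enf1-6 minus Col in blue and enf1-1 minus Col in orange (216 runs and the 5 at the start of chromosome 3). The 5 runs at the start of chromosome 3 stand between 0.37 and 0.47 in enf1-6 and between 0.01 and 0.08 in enf1-1.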

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

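All tests here except the random splits and the search for outliers were chosen after results were seen, the sizes of 100 genes after neighbouring genes had been noticed, and no other sizes were tried. The splits were redrawn once, after a first draw had let the 4 Col arrays stay together as Col in some splits, which nearly repeats the real grouping. Which counts exceeded chance was the same in both draws.

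Chance is argued against for the counts of changed genes against Col, but only among splits that take no account of slide. Of 100 splits of the 10 arrays into groups of 4, 3 and 3 that part the Col arrays otherwise, the real one included, 1 gave as many changed genes as the 7760 for the mean of both alleles (highest other 269) and 1 as many as the 4377 for both alleles (highest other 0). Of 35 splits of the 7 arrays, 1 gave as many as the 5057 in enf1-1 (highest other 905) and 1 as many as the 7225 in enf1-6 (highest other 4763, in the split that calls Col replicates 1, 3 and 4 the mutant and so nearly mirrors the real one). For the 4 gene lists, 51 of 100 splits gave as many, with up to 8, so chance is not excluded for their number. For enf1-6 against enf1-1 the 10 splits are too few for a share under 0.05; 1 gave as many as the real 9, and the highest other was 0. Within slides the arrays called Col can be chosen in only 9 ways, too few for a share under 0.05. Chance combined with slide is therefore not excluded by these splits. A split that calls the arrays of scan day 1 Col gave 0 changed genes for the mean of both alleles and 3 lists.

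Of 105 named genes, 9 had a Col array far from the other 3; chance gives about 1 in 20. Col replicate 3 was low for RIC10 (-3.55), YAB5 (-0.09), GLU1 (2.19) and RVE8 (-2.88). Col replicate 2 was low for AIL7 (-3.72) and high for SDD1 (0.7). Col replicate 1 was low for CYCB2;1 (-0.93) and CSY4 (1.83), and Col replicate 4 was low for LOX2 (4.79).

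Between the alleles, the fitted difference was 4.89 for AT3G01345, 6.06 for AT5G24240, 4.65 for AT5G24250 (at least 6.28-fold) and 1.12 for AT3G06145. For 3 probes that the array names only by a position it was 3.2 on chromosome 1, -1.84 on chromosome 2 (at least 3.53-fold) and -3.3 on chromosome 5 (at least 8.73-fold). For 2 probes with accessions alone it was 3.9 (at least 4.67-fold) and -1.48 (at least 2.79-fold). The lists called between the alleles had median differences of -0.15 (adaxial genes), 0.43 (photosynthesis), -0.21 (anthocyanin) and 0.6 (seed storage).

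The first pattern is that enf1-1 replicate 3 lies nearer to Col than the other enf1 arrays. Col RNA mixed into that sample would give the same share from risen and fallen genes, but the shares were 47.5% and 15.2%, a difference of 32.3 points (bootstrap SE 1). By the bound of 10 points written beforehand this would argue against a mixture. A control added after that value was seen gave -33.5 points for enf1-1 replicate 1 and 15.9 for enf1-6 replicate 3. The other enf1 arrays stayed within the bound (8.77 for enf1-1 replicate 2, -1.18 and 3.39 for enf1-6 replicates 1 and 2). Since some control arrays broke it, the bound does not tell a mixture from spread between arrays, and the test is now read as undecided. The share in enf1-1 replicate 3 from ALDH5F1 alone was 8.96%, but 1 gene decides nothing. A shift of the whole slide left a displacement of -24.8 on the first component (SD of the other arrays about 17), which decides nothing either, and no biological explanation was tested.

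The second pattern is that genes differing between the alleles lie together. Of the 100 genes with the smallest p, 70 were on chromosome 3, and the fullest window of 100 neighbouring genes held 18, against at most 7 in 10000 random placements (permutation p = 1e-04, the smallest they can give; 11 with slide as a block, in a window that shares 13 genes with the first), as a chromosome segment that differs between the lines would give. Probes weakened by sequence differences are argued against, since 11.1% of these 18 genes were lower than Col in the farther allele (exact binomial 95% interval 1.38% to 34.7%). An extra copy of the segment in enf1-6 may be a cause: the window's other 82 genes had a median difference of 0.38 (bootstrap SE 0.01), just under the 0.4 set beforehand as its lower bound, with 0.58 for 3 copies against 2, so it stays open. Leaving out the top genes, whose values had been seen when the bound was written, lowers that median by construction, and no DNA was measured.

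The third pattern is that photosynthesis and stomatal genes were lower and meristem genes higher in enf1. A lower share of leaf cells in the samples stays open: the medians of vascular, trichome and root markers had a range of 0.24 (permutation p = 0.63), but veins and trichomes are parts of the leaf, so the test is void. An earlier test of meristem against vascular markers is not used, since meristem genes are part of the pattern. Scan day is argued against, since the smallest of the 3 lists' medians within a day was 0.88 in size with its direction kept. A larger share of meristem cells in the enf1 apices and a change of expression within cells both stay open as untested.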

How the results depend on the processing

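ALDH5F1 stayed lower than Col under each alternative run, although in enf1-6 it did not pass on day 1 alone, and the same 4 lists were called under each alternative except camera with an estimated correlation. Alternative respiration was called as well with normexp, the deposited values and slide as a fixed or random block, TCA cycle genes with normexp and heat shock genes on day 1 alone. Of 127 values of named genes, 25 kept their direction but lost the call with slide as a fixed block, 42 on the slides with all 3 groups, 22 on the deposited values, 11 with the replicate block and 55 on day 1 alone. Over all alternatives and left-out arrays 68 lost the call at least once, most often VND7, GL3, REV, PHB, PAP1 and CRU3. On the deposited unscaled values the counts were 4681 (mean of both alleles; 40.2% higher against 54.5%), 2915 (enf1-1), 4397 (enf1-6; 25.4% higher against 55.6%) and 2210 (both alleles). With slide as a fixed block they were 4859, 3336 for enf1-1 and 4 between the alleles, and on the slides with all 3 groups alone 3716, 1225, 3716, 1153 for both alleles and 3 between the alleles, where fewer arrays remain. With scan day 1 alone, added after the data were seen, they were 1218, 578, 396, 288 and 4. With array weights enf1-1 had 7639, both alleles 6581 and the allele difference 14. Probes above background on all arrays gave 3 allele differences. A change of at least 1 on the log2 scale left 2587, 2240, 2886 and 1815. Camera with an estimated correlation called 0 lists and fry 10, the 4 among them. The cause was not tested, apart from the smaller number of arrays or the stricter threshold where these are named. The deposited values are an exception: apart from 1 or 2 spots per array they differ from the main values only by the missing scaling. The 75th percentiles that the scaling takes off were 2871 to 3032 in enf1-6 and 2698 to 4395 in Col.

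The replicate numbers do not pair all arrays: 5 of 9 pairs of the same number correlated over 0.1, and 4 of 10 arrays correlated best with their own number. The 3 pairs of enf1-1 and enf1-6 with the same number shared a slide and are among the 5. All 7 pairs of different groups on the same slide correlated over 0.1 (0.16 to 0.46). With the replicate number as a block (replicate block), 4 features differed between the alleles.

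Leaving out each array in turn gave 5785 to 9366 for the mean of both alleles, 3134 to 5367 for enf1-1, 4380 to 9369 for enf1-6, 4 to 9 between the alleles, 2903 to 4821 for both alleles, -3.07 to -2.7 for ALDH5F1 and 4 to 4 lists. Counts moved by over 1.5 times without enf1-1 replicate 1 (3134 for enf1-1, 2903 for both alleles) and without enf1-6 replicate 1 (4516) or 2 (4380); between the alleles there were 5 without Col replicate 4, enf1-1 replicate 3 or enf1-6 replicate 1 and 4 without enf1-1 replicate 2 or enf1-6 replicate 3.

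FIL, near 0 and not called, changed sign for the mean of both alleles with the deposited values (-0.11), slide as a fixed block or slides with all groups (-0.18 each), slide as a random block (-0.03), array weights (-0.04), and without Col replicate 1 (-0.04), Col replicate 2 (-0.02) or enf1-6 replicate 1 (-0.03). In enf1-1 it turned with slide as a block (-0.12), slides with all groups (-0.06) and array weights (-0.02). In enf1-6 it turned with normexp (0), the replicate block (0.03), day 1 alone (0.34), and without Col replicate 3 (0.01), Col replicate 4 (0.03) or enf1-6 replicate 2 (0.11). Between the alleles it turned without enf1-6 replicate 2 (0.03) and on day 1 alone (0.15). Without a change of sign it moved to 0.09 for the mean of both alleles without Col replicate 4, and without enf1-6 replicate 1 to -0.14 in enf1-6 and -0.22 between the alleles.

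The fit with only the groups compared does not apply to the mean of both alleles, and every probe on its own was not planned for lists. Genes not well above background have only bounds.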

Other observations

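The tests on the lists below, of genes other than those of the 26 lists for the most part, were chosen after the named genes were seen, and each list was tested only on members whose values had not been seen; they make 4 tests. The comparison of these lists between the alleles and the counts over all members were added later. Between the alleles, camera did not call the lists of mitochondrial dysfunction (adjusted p = 0.92) and of other microRNA targets (adjusted p = 0.089).

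DNA damage response genes rose in enf1. After NAC085, NAC044 and GMI1 had been seen among the risen genes, 12 further genes were tested, and 11 rose and 0 fell, also adjusted over the list alone. The cell cycle inhibitor genes SMR7 and SMR5 rose by 3.43 (SE 0.26) and 3.3 (SE 0.24) on the log2 scale, the poly(ADP-ribose) polymerase gene PARP2 by 1.48, RAD17 by 1.24, XRI1 by 1.17 and BRCA1 by 0.9. BARD1 did not pass (-0.07). The median was 0.74 against 0.06 for all features (camera p = 6.9e-08, adjusted p = 2.8e-07; adjusted p = 0.022 with an estimated correlation). Between the alleles, 9 of the 12 were lower in enf1-6, and camera placed the list lower there (median difference -0.05, adjusted p = 0.041; adjusted p = 0.27 with an estimated correlation). These values are consistent with the hypothesis of higher expression of DNA damage response genes in both alleles; what would raise them was not tested.

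Genes that respond to mitochondrial dysfunction were tested after TIM17-1, NDB4, UPOX and AOX1A had been seen. Of 11 further genes, 5 rose and 0 fell, or 7 and 0 adjusted over the list alone, with a median of 0.67 (camera p = 0.00067; adjusted p = 0.084 with an estimated correlation). OM66 rose by 2.52, CYP81D8 by 1.57 and MGE1 by 0.67 on the log2 scale, while AT12CYS-2 (0.3) and UGT74E2 (0.82) did not pass. Fewer rose than the share of the list set beforehand as the bound, so higher expression of the targets as a group stays undecided. The 11 leave out TIM17-1 and NDB4, already seen to rise. Over all 13 members 7 rose and 0 fell, with a median of 0.82. Counts that include genes picked for their rise are no test.

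SPL genes that the microRNA miR156 targets were tested after SPL3 had been seen to fall and SPL9 not to pass. Of 8 further genes, 0 rose and 5 fell, also adjusted over the list alone, and their median was -1.35 (camera p = 0.00031, adjusted p = 0.00062; adjusted p = 0.27 with an estimated correlation). SPL4 fell by 1.93, SPL15 by 1.5, SPL11 by 1.43, SPL5 by 1.3 and SPL6 by 0.85 on the log2 scale. Their limma adjusted p-values were 0.00012, 0.033, 0.0094, 0.025 and 0.046 in that order, some of them near the threshold. SPL6 changed by -0.31 in enf1-1 and by -1.39 in enf1-6. All 8 were lower in enf1-6 than in enf1-1, with medians of -1.97 and -0.72. None of the 8 differences passed limma's test on its own, 4 had an unadjusted p under 0.05, and camera placed the list lower in enf1-6 (adjusted p = 8e-07; adjusted p = 0.27 with an estimated correlation). The values may reflect lower expression of these SPL genes as a group, more so in enf1-6, for which both calls are lost with an estimated correlation.

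A fall of microRNA targets as a whole stays undecided. Of 19 further targets of other conserved microRNAs 6 rose and 1 fell, also adjusted over the list alone, with a median of 0.13 (camera p = 0.46; adjusted p = 0.65 with an estimated correlation). By the bound written beforehand this would argue against it, but the bound was wrong, since these 19 leave out the members already seen. More of those had fallen, such as CSD2 (-2.34) and TCP3 (-1.09), than had risen, namely CUC1 (1.59), CUC2 (0.9) and GRF3 (0.58). Over all 36 members 9 rose and 8 fell, with a median of -0.12. Putting the seen members back therefore showed no fall of most targets.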
